A study of Homo sapiens with 36 samples.

How the data were processed

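Poly(A) RNA libraries (TruSeq Stranded mRNA, per the labels' protocols) of 6 H446 clones, with 3 libraries per clone and treatment, were analysed from 2 deposited tables. Reads were processed with cutadapt, STAR and RSEM on the human genome build hg19, per the submitters' processing notes; the order of the steps and the versions are not given in the sources used here. The first table holds 19014 genes with the authors' DESeq2-normalized counts, a signal of gene counts divided by 1 size factor per library; the rule by which these genes were kept is not given in the sources used here. The second holds the authors' deposited RSEM values of 57820 genes in FPKM, which is scaled by gene length and library size. In the table of normalized counts every column was a whole multiple of its smallest step (100% of values within 1e-06), so whole reads per gene were recovered from the deposited values, 13282337 to 31825795 per library with a median of 16302452. In 2 of the columns the size factor lies within 1% of 1 (0.9926 and 1.0007), so the step there is close to a whole read. A normalized count is corrected for depth and composition but not for gene length. Counts per gene were deposited without a measure of reads shared between near-identical copies, so single values of histone and other multicopy genes are uncertain, and 62 gene symbols stand on more than 1 gene.

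Groups and replicate numbers came from the labels, and the genotype, the treatment, the tests, the gene lists, the rule for named genes and all alternatives were fixed before the data were examined, except those said to be chosen later. Replicate libraries of a clone share its genome, so they were averaged and the clone was the replicate. Because normalized values rather than raw counts were deposited, tests used log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, with an expression trend in the prior variance. Genes with at least 10 normalized counts in at least 9 of the 36 libraries were tested (15819 genes). Genotype was tested on 3 against 3 clone means, separately with DMSO and with JQ1. JQ1 was tested on the JQ1 minus DMSO difference of each clone, with 1 estimate of the spread over the 6 clones, and the difference in response as knockout minus control clones in the same model. All p-values are two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and every adjusted p of a single gene is from limma unless edgeR or DESeq2 is named. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes. Where a group held 0 reads, a lower bound against a floor of 3 reads over the group is given, and where it held 1 to 3, the ratio with its 95% interval, both for counting error only.

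The 38 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists within a comparison. Beside the count of members past the threshold over all genes stands the count with p adjusted over the list alone. Named genes were NEUROD1, MYC, HEXIM1 and BCL2, 2 further genes that are not reported here, the 10 largest rises and 10 largest falls per comparison (5 and 5 for genotype with JQ1) among genes past the threshold with a mean of at least 50 and 1 direction in every clone, and up to 4 members past the threshold, or else up to 2 of the highest mean, of each list described. Lung, blood and stroma transcripts of the library that stood apart were chosen after their values were seen, apart from the markers in the lists. Genes in GENCODE 29 on GRCh38 (97.03% of the genes tested, 15349) gave gene type and order along chromosomes and the position of NEUROD1; no hg19 coordinates were used.

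Alternatives were other pseudocounts and filters, equal library totals, TMM, FPKM (offset 0.1), other priors, single libraries as replicates with and without a block for the replicate number, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads summed per clone and treatment, a 2-fold minimum, and leaving out each clone, replicate number and library. For JQ1 within a genotype, the spread was also estimated from the clones of that genotype alone. Each test was tried on simulated data: 4-fold changes were recovered for 64.6% of changed genes for genotype with DMSO, 92% for JQ1 in control clones and 87.8% for the difference in response, over 15669 genes, and 4.42% to 5.71% of calls were unchanged genes. The simulation changed far fewer genes than passed in the data (77 calls against 1985 for genotype with DMSO). It also held no library with foreign transcripts, so these shares need not hold for the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.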

Results

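RNA was sequenced from H446, an established human small-cell lung cancer line that expresses the neural transcription factor NEUROD1. The 36 libraries came from 6 clones: 3 control clones with a non-targeting guide RNA (clones 3, 10 and 13) and 3 clones in which NEUROD1 had been knocked out (clones 12, 15 and 2-1). Each clone was treated for 24 h with 1 µM JQ1, a small molecule that displaces BET bromodomain proteins from acetylated histones, or with its solvent DMSO. The labels give the same NEUROD1 guide RNA for every knockout clone and 3 biological replicates per clone and treatment. The clone was the unit of replication for genotype, so each level is a mean of normalized counts ± SD over 3 clones (n = 3), and each log2 fold change carries its standard error (SE).

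The normalized counts gave back 13282337 to 18890506 whole reads per library in all libraries but 1, with a median of 16302452 over all 36. Replicate libraries of a clone differed by more than counting noise (chi-square per degree of freedom at least 2.19 over pairs of replicates), so none looked like a library deposited more than once. It was at most 14.0 but for the library of knockout clone 12 with JQ1, replicate 1, which stood apart (341.4 and 295.5 against its replicates). It held 31825795 reads, and 8.82% of them came from 6 short structural RNAs that lack poly(A) tails, against 0.00198% to 0.0188% in the others. It also held lung and blood transcripts that its replicates lacked. CEACAM6, an adhesion molecule of glandular epithelium, stood at 46010 normalized counts in it, at 80.4 in control clone 13 with JQ1, replicate 1, and at 0 in the other 34 libraries. SFTPA2, a lung surfactant protein, stood at 12390 and CD74, an invariant chain of antigen-presenting cells, at 10290, against 0 and at most 1.17 in the other 2 replicates. Genes well expressed in its replicates were mostly lower in it. Over 4149 genes with a mean of at least 1000 there, the median ratio of this library to them was 0.77. Levels of knockout clones with JQ1 include this library. The number of genes past the threshold in each comparison that uses this library is therefore also given without it. This choice was made after its content was seen. Counts at a 2-fold minimum, counts and correlations shared between comparisons and some list counts are given with it only.

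**Figure D1:**
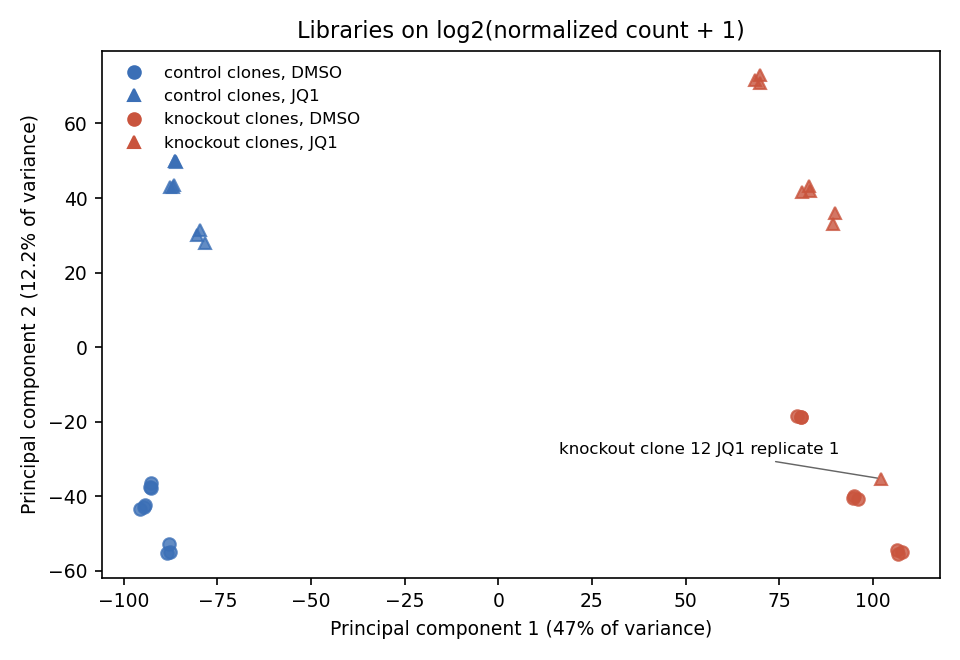
Position of each of the 36 libraries on the first 2 principal components of log2(normalized count + 1), by genotype (colour) and treatment (shape); the axes give the share of variance, 47% and 12.2%. Component 1 separates knockout from control clones and component 2 separates JQ1 from DMSO, except for replicate 1 of knockout clone 12 with JQ1, which lies at -35.27 on component 2 while its replicates lie at 33.14 and 35.98.

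**Figure D2:**
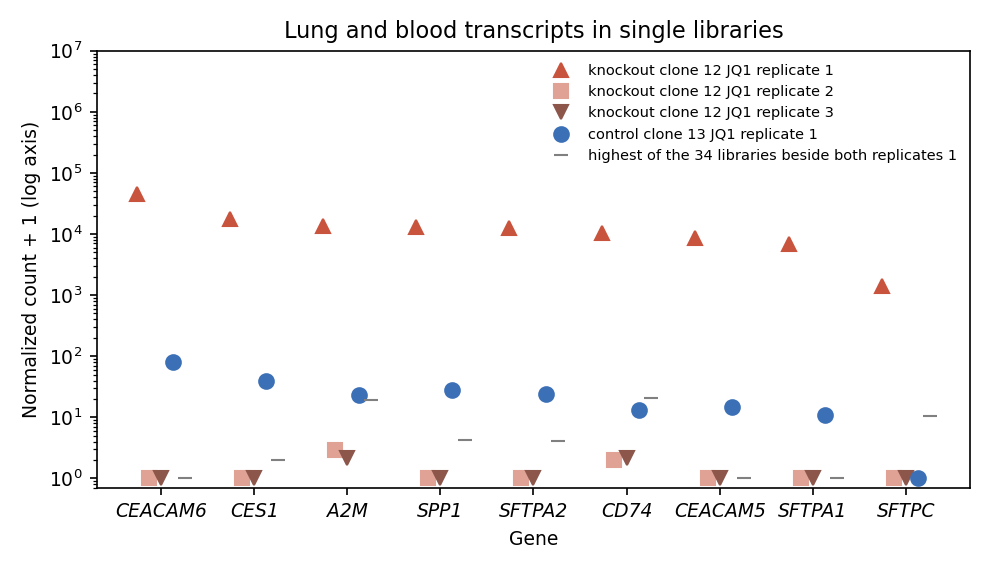
Normalized counts + 1 (log axis) of 9 lung and blood transcripts in replicate 1 of knockout clone 12 with JQ1, in its 2 replicates, in control clone 13 with JQ1, replicate 1, and the highest value among the other 34 libraries. In the first library they range from 1407 (SFTPC) to 46010 (CEACAM6).

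The knocked-out gene was examined first. NEUROD1, a basic helix-loop-helix factor of neuronal and endocrine differentiation, lies in GRCh38 on the minus strand of chromosome 2 (181673088 to 181680876). Its level was 5998 ± 580.5 in control clones with DMSO and 1.87 ± 2.93 in knockout clones, 0.0312% of the control level (log2 fold change -11.55, SE 0.67, adjusted p = 0.000187, limma). With JQ1 the levels were 7092 ± 1266 and 2.42 ± 3.60. The 6 libraries of knockout clone 15 held 0 NEUROD1 reads, those of clone 12 held 4 and those of clone 2-1 held 36.

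**Figure D3:**
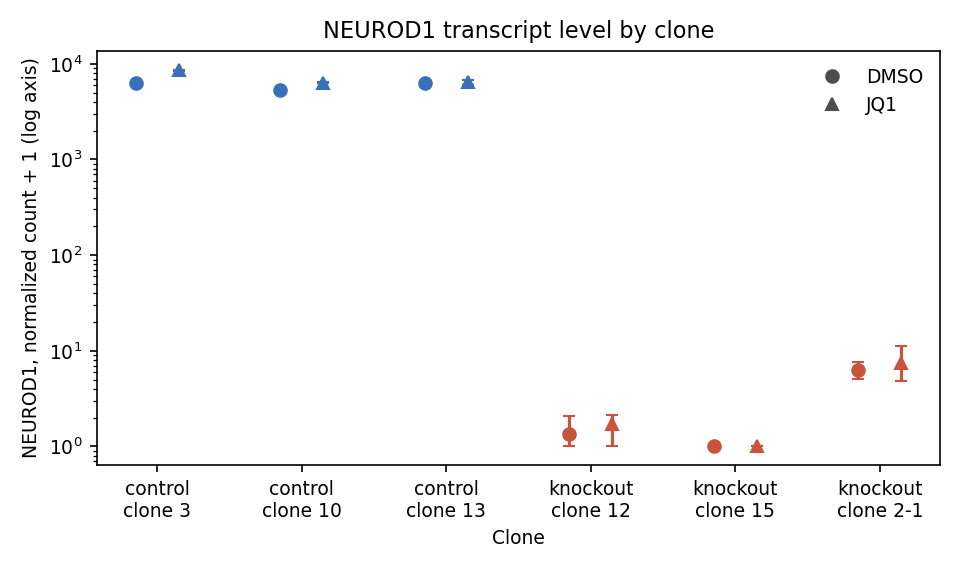
NEUROD1 level per clone as normalized count + 1 (log axis), with DMSO (circles) and JQ1 (triangles), control clones in blue and knockout clones in red. Symbols are means of 3 libraries and bars span the lowest to the highest library; control clones lie between 5328 and 8553 and knockout clones at 6.55 or lower.

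The comparison of knockout with control clones in DMSO asks which transcripts depend on NEUROD1 in these cells. Loss of NEUROD1 went with loss of neuronal and secretory transcripts and with gain of transcripts of epithelial, basal and mesenchymal cells. SEZ6L, a neuronal membrane protein, fell from 4871 ± 1312 to 0.786 ± 0.772 (log2 fold change -11.55, SE 0.37, adjusted p = 2.65e-05). SYT4, a synaptotagmin of secretory vesicles, fell from 4131 ± 604.3 to 0.809 ± 0.423 (log2 fold change -11.25, SE 0.29, adjusted p = 2.03e-05). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 1.86 ± 1.30 to 22530 ± 8523 (log2 fold change 13.13, SE 0.46, adjusted p = 3e-05). MET, the receptor of hepatocyte growth factor, rose from 2.11 ± 0.941 to 3578 ± 3446 (log2 fold change 9.20, SE 1.29, adjusted p = 0.00649). Of 15819 genes tested, 1985 differed, 1000 higher and 985 lower in knockout clones, and 1614 of them changed at least 2-fold (812 higher, 802 lower). All 1985 lay on the same side in every knockout clone.

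Among the largest falls, GRIK3, a kainate receptor subunit, went from 4708 ± 1655 to 1.13 ± 1.22 and CPLX2, a complexin of synaptic release, from 2475 ± 818.4 to 0.482 ± 0.835. OAS1, an interferon-induced oligoadenylate synthetase, went from 16390 ± 10060 to 1.63 ± 1.14 (log2 fold change -12.64, SE 0.54, adjusted p = 7.83e-05). RPH3A, a rabphilin of vesicle exocytosis, had 2 reads in the 9 knockout libraries against 33727, a ratio of 16500 (95% counting interval 4580 to 137000). STMN2, a regulator of neuronal microtubules, and KCNJ6, an inward rectifier potassium channel, had 1 read each there, with ratios of 16700 (2990 to 659000) and 19500 (3510 to 771000). NEUROD4, a related neural helix-loop-helix factor, stood at 1488 ± 183.1 in control clones and at 0 in every knockout library, at least 4380-fold lower. All of these passed the test at an adjusted p of 7.83e-05 or lower.

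Among the largest rises, SLC27A6, a fatty acid transporter, reached 4643 ± 1254 in knockout clones from 2 reads in all control libraries (ratio 21200, 5860 to 175000). FBN2, a microfibril protein of the matrix, reached 28590 ± 26880 there from 1 read (ratio 247000, 44400 to 9770000). PLEKHA2, an adaptor with pleckstrin homology domains, rose from 3.50 ± 4.90 to 1854 ± 578.8 and KRT75, a keratin, from 0.711 ± 0.721 to 3586 ± 3339. TP63, a factor of basal epithelium, reached 8582 ± 10720 (ratio 36700, 10200 to 303000) and TGFA, a ligand of the EGF receptor, 6659 ± 7301 (ratio 57600, 10300 to 2270000), each with a spread between clones above its mean. SERPINB5, an epithelial serpin, reached 767.2 ± 563.3 (ratio 7070, 1270 to 279000), and CHI3L1, a secreted chitinase-like protein, reached 808.9 ± 646.4 from 0, at least 2360-fold higher. Their adjusted p lay between 2.03e-05 (SLC27A6) and 0.0264 (TGFA).

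Gene lists of neuroendocrine and neuronal cells moved down. Of 22 genes of a published neuroendocrine score for this cancer, 19 fell and 0 rose (21 and 0 adjusted over the list alone). Their median log2 fold change was -4.48 (camera adjusted p = 1.11e-21, and adjusted p = 2.26e-10 with an estimated correlation). CHGA, the granule protein chromogranin A, fell from 3492 ± 771.8 to 18.8 ± 11.5 (log2 fold change -7.63, SE 0.43), SEZ6 from 4277 ± 1984 to 11.4 ± 9.47 and CELF3 from 512.4 ± 177.1 to 1.46 ± 1.05. Neural transcription factors fell in 18 of 38 cases and rose in 1 (24 and 4 over the list alone; median -1.40, adjusted p = 2.46e-11). PAX5 fell from 1242 ± 220.9 to 1.81 ± 1.19, BHLHE22 from 3222 ± 1090 to 10.1 ± 12.6 and ST18 from 685.7 ± 42.77 to 0, at least 2030-fold lower. Of 20 genes linked to NEUROD1 in the literature, 13 fell and 0 rose (17 and 0 over the list alone; median -3.94, adjusted p = 5.25e-15). Synaptic vesicle and exocytosis genes fell in 21 of 40 cases and rose in 1 (25 and 2 over the list alone; median -1.91, adjusted p = 1.34e-12). UNC13A, a vesicle priming factor, fell from 5310 ± 1005 to 32.0 ± 25.6. Voltage-gated channel genes fell in 12 of 27 cases (19 over the list alone; median -2.39, adjusted p = 5.16e-10), and KCNA1 went from 7914 ± 2281 to 44.9 ± 51.2. Axon guidance and adhesion genes fell in 14 of 33 cases and rose in 1 (18 and 4 over the list alone; median -1.61, adjusted p = 9.08e-07). The netrin receptor DCC fell from 614.4 ± 116.6 to 1.97 ± 3.10 and GAP43, a growth cone protein, from 3272 ± 219 to 14.3 ± 7.49.

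Nicotinic receptor subunits went both ways. CHRNA3 fell from 2436 ± 1523 to 10.6 ± 3.02 and CHRNB2 from 2159 ± 440.2 to 32.8 ± 22.1, while CHRNA9 rose from 0.665 ± 0.579 to 859.0 ± 524.1 (log2 fold change 9.06, SE 0.51, adjusted p = 0.000187). Of 8 subunits, 4 fell, 1 rose (5 and 2 over the list alone), and the list did not pass its test (adjusted p = 0.0842). Of 11 peptide hormone genes, 5 fell and 2 rose (6 and 2 over the list alone; adjusted p = 0.0198). The prohormone convertase PCSK2 fell from 629.5 ± 276.1 to 2.82 ± 2.89 and the calcitonin gene-related peptide CALCB rose from 2.60 ± 0.934 to 691.7 ± 934.6. Sterol synthesis and uptake genes fell in 13 of 24 cases and rose in 0 (18 and 0 over the list alone; median -1.23, adjusted p = 8.87e-10, and adjusted p = 0.0383 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, fell from 6423 ± 1135 to 1465 ± 282.4 (log2 fold change -2.14, SE 0.20) and SREBF2, the factor that drives these genes, from 5231 ± 204.1 to 1606 ± 237.4 (log2 fold change -1.71, SE 0.14).

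Genes of non-neuroendocrine cells moved up. Of 18 genes of the non-neuroendocrine score, 10 rose and 0 fell (12 and 0 over the list alone; median 4.22, adjusted p = 6.14e-08). S100A10 rose from 2.41 ± 2.21 to 399.3 ± 133.1, AHNAK from 32.3 ± 18.5 to 3190 ± 1154 and IFITM3 from 1.25 ± 1.64 to 206.5 ± 165.4. Mesenchymal and matrix genes rose in 12 of 29 cases and fell in 2 (15 and 2 over the list alone; median 1.74, adjusted p = 2.5e-05). TGFB1 rose from 7.96 ± 3.91 to 828.4 ± 110.6 and TIMP1 from 3.75 ± 1.45 to 1525 ± 1682. Epithelial adhesion genes rose in 4 of 12 cases (5 over the list alone; median 1.59, adjusted p = 0.00106), with JUP, the desmosomal protein plakoglobin, from 113.9 ± 36.5 to 554.2 ± 126.2. Of 4 lung epithelial markers, KRT5 and TP63, which mark basal cells, and AVIL, which marks tuft cells, rose (median 5.70, or 6.63 with KRT5 at its bound; adjusted p = 0.00355); KRT5 reached 1070 ± 902.4 from 0, at least 3210-fold higher. YAP1, a co-activator that is silent in most neuroendocrine lung cancer, stood at 0.217 ± 0.376 in control and at 81.5 ± 76.0 in knockout clones (adjusted p = 0.00853). Of 26 genes of a list of YAP and TAZ targets that also holds YAP1 itself, 7 rose (7 over the list alone; adjusted p = 0.00204, but adjusted p = 0.217 with an estimated correlation), the receptor kinase AXL among them at 155.8 ± 168.9 from 1 read. Notch pathway genes went both ways (5 of 24 higher, 3 lower, 8 and 3 over the list alone; adjusted p = 0.283). HES1, a repressor of neuroendocrine genes, rose from 3.14 ± 2.93 to 126.1 ± 45.6 and NOTCH1 from 28.0 ± 15.9 to 447.8 ± 189.8, while HES6 fell from 1489 ± 596.0 to 172.1 ± 58.2.

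Interferon-stimulated genes split as well (7 of 21 higher, 3 lower, 8 and 3 over the list alone; adjusted p = 0.335), since OAS1 and OAS3 fell and PARP12, from 0.111 ± 0.192 to 22.6 ± 13.7, rose. MYC stood at 1911 ± 913.8 in control and at 827.1 ± 306.7 in knockout clones, a difference within the spread between clones (log2 fold change -1.12, adjusted p = 0.175). The 10 MYC family genes did not stand apart as a list (adjusted p = 0.896). HEXIM1 and BCL2 did not pass the test either. Proliferation lists moved little: G1/S genes fell in 2 of 55 cases (1 over the list alone; median -0.29, adjusted p = 0.00117, but adjusted p = 0.138 with an estimated correlation). With 3 clones against 3, a simulated 2-fold change was recovered for 18.4% of changed genes and a 4-fold change for 64.6%, so a gene that missed the test here is not shown to be unchanged. Without control clone 3, 10 or 13 the test gave 1216, 906 or 1119 genes.

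**Figure D4:**
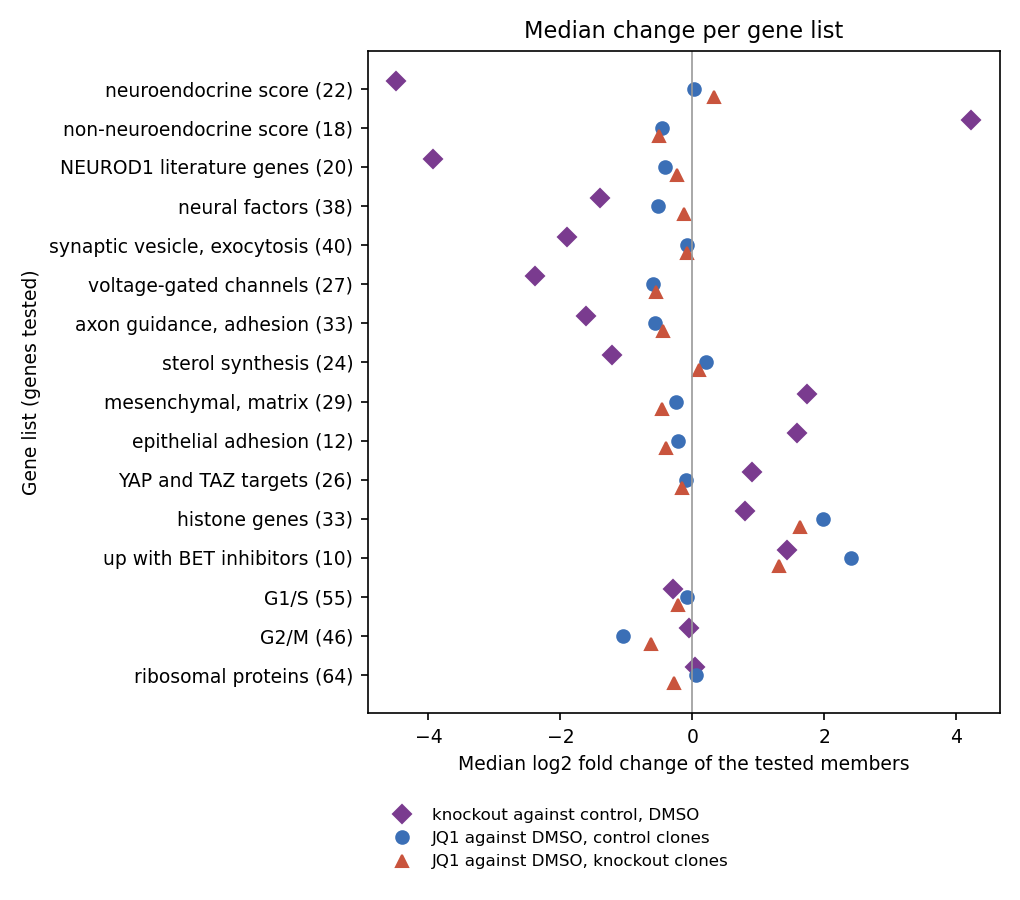
Median log2 fold change over the tested members of 16 gene lists (number of genes in parentheses) for knockout against control clones in DMSO and for JQ1 against DMSO in each genotype. The knockout medians run from -4.48 (neuroendocrine score) to 4.22 (non-neuroendocrine score); the JQ1 medians of histone genes are 1.98 in control and 1.63 in knockout clones, without error bars because each is a median over genes.

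With JQ1 present, the same contrast between genotypes gave 1893 genes, 1008 higher and 885 lower in knockout clones, and 1766 (891 and 875) without the library that stood apart, 1613 of them shared. PDK4 stood at 28760 ± 10060 in knockout clones against 3 reads in all control libraries (ratio 80000, 27400 to 388000), SLC27A6 at 1532 ± 374.4 against 0 (at least 4310-fold higher), and MET at 2563 ± 2120 against 0.732 ± 0.787. STMN2 (2479 ± 838.1 in control clones), SEZ6L (2515 ± 1144), SYT4 (1774 ± 148.8) and MYBPC1, a myosin-binding protein (1645 ± 904.2), stood at 0.125 to 1.51 in knockout clones. Of the neuroendocrine score 19 of 22 genes were lower (18 without that library; 21 over the list alone; adjusted p = 4.11e-24), and INSM1, a factor of neuroendocrine differentiation, stood at 2703 ± 283.5 against 28.6 ± 6.57. G1/S genes were lower in 13 of 55 cases and higher in 1 (17 and 1 over the list alone; adjusted p = 2.02e-08; 9 and 0 without that library), among them UHRF1, at 5207 ± 713.6 against 2255 ± 117.7. Epithelial adhesion genes were higher in 3 of 12 cases (7 over the list alone; adjusted p = 0.000421, but adjusted p = 0.097 with an estimated correlation; 2 without that library). The genotype effects in DMSO and in JQ1 correlated across genes (r = 0.931), with 653 genes higher and 655 lower in both, where independent lists of these sizes would share 63.7 and 55.1, and 0 called in opposite directions. Both contrasts use the same clones, so lasting differences between clones would also be shared. Independent lists are therefore not the value for no effect. Without control clone 3, 10 or 13 the test gave 1095, 760 or 1068.

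JQ1 against DMSO within clones asks what BET inhibition does to this transcriptome, first with NEUROD1 present. In control clones HEXIM1, a repressor of the elongation kinase P-TEFb that serves as a marker of BET inhibition, rose from 458.6 ± 29.3 to 2138 ± 170.0 (log2 fold change 2.22, SE 0.07, adjusted p = 9.1e-06). BRD2 rose from 3899 ± 769.1 to 11930 ± 3090 (log2 fold change 1.60, SE 0.07). MYC rose rather than fell, from 1911 ± 913.8 to 3808 ± 1332 (log2 fold change 1.08, SE 0.13, adjusted p = 0.000319). NEUROD1 itself (log2 fold change 0.23, SE 0.14, adjusted p = 0.19) and BCL2 did not pass the test. In all, 7572 genes changed, 3636 higher and 3936 lower, and 2002 changed at least 2-fold, 620 higher and 1382 lower. The spread used here is shared with the knockout clones, and without the library that stood apart 8294 genes passed (3977 and 4317). With a spread from the control clones alone 9319 passed (4501 and 4818).

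Histone genes led the rises: 28 of 33 rose and 0 fell (29 and 0 over the list alone, median 1.98, adjusted p = 5.46e-13, but adjusted p = 0.0614 with an estimated correlation). The libraries were made from poly(A) RNA, so histone transcripts without a poly(A) tail would be largely missed. The counts therefore need not follow the total transcript level of these genes. HIST1H2BC rose from 13.6 ± 5.31 to 227.7 ± 108.6 (log2 fold change 3.92, SE 0.22), HIST2H2BE from 175.8 ± 128.3 to 2134 ± 1375 (3.64, SE 0.14) and HIST1H4H from 31.7 ± 15.0 to 234.3 ± 64.2 (2.94, SE 0.16). HIST2H4B (6.02), HIST2H4A (3.49), HIST2H3A (3.67) and HIST2H2AA4 (3.48) rose too, but these genes have near-identical copies between which reads can be split, so their single values are uncertain. NPTX2, a neuronal pentraxin, rose from 128.6 ± 60.1 to 843.8 ± 257.8, and the non-coding AP000692.10 rose to 129.3 ± 104.0. Of 10 genes known to rise with BET inhibitors, 9 rose and 1 fell (9 and 1 over the list alone; median 2.41, adjusted p = 1.81e-05). SAT1, a polyamine acetylase, went from 123.9 ± 16.8 to 776.7 ± 134.3. Immediate early genes rose in 14 of 31 cases and fell in 3 (14 and 3 over the list alone; adjusted p = 0.0131, but adjusted p = 0.45 with an estimated correlation). FOS rose from 8.66 ± 1.19 to 46.6 ± 4.33.

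G2/M genes fell almost as a whole: 45 of 46 were lower and 0 higher (45 and 0 over the list alone; median -1.05, adjusted p = 3.74e-17, but adjusted p = 0.26 with an estimated correlation). FOXM1, the factor that drives mitotic genes, fell from 3317 ± 825.5 to 724.2 ± 122.7 (log2 fold change -2.18, SE 0.08, adjusted p = 9.52e-06). ESPL1, the protease separase, fell from 2032 ± 381.1 to 556.1 ± 66.1 and PRC1, a protein of the central spindle, from 2946 ± 49.9 to 1036 ± 187.8. G1/S genes went both ways, 18 higher and 18 lower of 55 (18 and 18 over the list alone; adjusted p = 0.847). CCNE2 rose from 817.2 ± 112.7 to 2540 ± 572.3 and E2F8 fell from 238.3 ± 12.0 to 67.2 ± 8.40. CDKN1A, the cell cycle inhibitor p21, rose from 4200 ± 847.7 to 15530 ± 2900 (log2 fold change 1.89, SE 0.17). In the BCL2 family, 6 of 18 rose and 2 fell (6 and 2 over the list alone; adjusted p = 0.357, but adjusted p = 6.38e-09 with an estimated correlation, which was negative and so lowers p). The pro-apoptotic PMAIP1 rose from 628.4 ± 87.9 to 2097 ± 444.9 and BCL2L11 from 314.5 ± 14.6 to 954.4 ± 127.1. MYC targets of ribosome biogenesis went both ways, 13 higher and 19 lower of 51 (15 and 21 over the list alone; adjusted p = 0.767).

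The largest falls were SLC15A3, a lysosomal peptide transporter, from 263.6 ± 245.7 to 6.03 ± 2.35 (log2 fold change -5.01, SE 0.50), and BANK1, a scaffold of B-cell receptor signalling, from 266.5 ± 75.2 to 10.9 ± 7.77 (-4.75, SE 0.24). HTR1A, a serotonin receptor, fell from 229.9 ± 110.5 to 12.8 ± 6.45 (-4.19, SE 0.24). GPR112 (-4.64), the non-coding CTD-2116F7.1 (-4.01), MYOF (-3.94), SEMA3D (-3.92) and MGAT3 (-3.79) fell as well. Axon guidance and adhesion genes fell in 17 of 33 cases and rose in 2 (19 and 2 over the list alone; median -0.57, adjusted p = 0.00123, and adjusted p = 0.000317 with an estimated correlation). DCX, the doublecortin of migrating neurons, fell from 605.3 ± 403.6 to 154.3 ± 112.8. Channel genes fell in 12 of 27 cases and rose in 2 (13 and 2 over the list alone; adjusted p = 0.0096, but adjusted p = 0.0614 with an estimated correlation). SCN2A fell from 595.2 ± 57.8 to 140.6 ± 24.1. Of 7 markers of stroma, 6 fell (6 over the list alone; median -1.71, adjusted p = 0.00669), COL1A2 from 3546 ± 1753 to 593.5 ± 417.9. Lists tied to the neuroendocrine state did not pass their tests. In control clones 4 genes of the neuroendocrine score rose and 2 fell of 22 (3 and 1 over the list alone; adjusted p = 0.606). Likewise 3 rose and 9 fell of 20 NEUROD1 literature genes (3 and 9 over the list alone; adjusted p = 0.269), and 7 rose and 18 fell of 38 neural factors (7 and 18 over the list alone; adjusted p = 0.149). Single members did: BHLHE22 fell to 313.5 ± 54.0, CHRNA3 to 364.3 ± 175.8 and RPH3A to 579.7 ± 321.1, while VGF, a secreted neuronal peptide, rose from 488.3 ± 130.1 to 3071 ± 1091. The balance of calls depended on scaling, since 2981 genes were higher and 4589 lower with equal library totals, and 2730 and 4074 with FPKM. Without control clone 10, 4945 genes passed.

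In knockout clones JQ1 changed 7845 genes, 3775 higher and 4070 lower, and 8922 (4141 and 4781) without the library that stood apart, 7554 of them shared. With equal library totals 3184 were higher and 4724 lower, and with FPKM 2914 and 4284. Of the 7845, 1869 changed at least 2-fold, 586 higher and 1283 lower. With a spread from the knockout clones alone 5616 genes passed (2688 and 2928), fewer than the 9319 in control clones with their own spread. The order of the 2 genotypes by number of genes thus depended on the shared spread. HEXIM1 rose from 716.1 ± 217.5 to 2643 ± 745.0 (log2 fold change 1.88, SE 0.07, adjusted p = 2.22e-05), BRD2 from 3263 ± 837.5 to 12220 ± 2187 (1.90, SE 0.07). MYC rose from 827.1 ± 306.7 to 2495 ± 930.5 (1.58, SE 0.13, adjusted p = 7.15e-05). CTGF, a matrix protein and YAP target, rose from 14.3 ± 7.52 to 457.5 ± 193.8 (4.79, SE 0.29), and TEX14 from 7.12 ± 4.09 to 119.5 ± 59.1 (3.89, SE 0.33). SLFN5, an interferon-induced schlafen protein, rose by 3.60 (SE 0.68, and 2.98 without that library). Histone genes rose in 28 of 33 cases and fell in 1 (28 and 1 over the list alone; median 1.63, adjusted p = 2.11e-10, but adjusted p = 0.0722 with an estimated correlation; 26 and 1 without that library). HIST2H3A (4.93), HIST2H3C (4.62), HIST2H4B (4.29), HIST2H4A (3.39) and F8A3 (3.73) were again genes whose reads can be shared with a copy. The limit that poly(A) libraries set for histone genes holds here too. TUBB3, a neuronal tubulin, rose by 3.56 in 1 entry of a symbol that stands on more than 1 gene.

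Among the largest falls in knockout clones were HTR1A, from 151.9 ± 103.8 to 5.24 ± 4.86 (log2 fold change -4.76, SE 0.24), and EDN2, the peptide endothelin 2, from 145.3 ± 88.2 to 8.68 ± 1.40. CHRNA9 fell from 859.0 ± 524.1 to 76.0 ± 36.4 and KRT80, a keratin, from 861.8 ± 614.5 to 125.2 ± 90.3 (-3.50, and -4.10 without the library that stood apart). TRAC (-4.35), SLC14A1 (-4.09), ACSL5 (-3.97, and -4.86 without that library), ACTBL2 (-3.62), MIR205HG (-3.43, and -4.21 without it) and RGS11 (-3.39) fell as well. G2/M genes fell in 41 of 46 cases and rose in 0 (41 and 0 over the list alone; median -0.64, adjusted p = 2.11e-10, but adjusted p = 0.427 with an estimated correlation; 38 without that library). FOXM1 fell from 2774 ± 19.3 to 1065 ± 97.8 and TOP2A from 23220 ± 6929 to 8970 ± 4027. Ribosomal protein genes fell in 46 of 64 cases and rose in 0 (48 and 0 over the list alone; median -0.28, adjusted p = 6.99e-09, but adjusted p = 0.465 with an estimated correlation; 47 and 1 without that library). RPL29 fell from 6039 ± 825.6 to 3447 ± 595.6. Mesenchymal and matrix genes fell in 11 of 29 cases and rose in 2 (11 and 2 over the list alone; adjusted p = 0.0171, but adjusted p = 0.0517 with an estimated correlation), and in 20 and 2 without that library. It held 32670 normalized counts of the collagen COL3A1 against a mean of 2468 in its replicates. KRT5 fell from 1070 ± 902.4 to 132.3 ± 118.6 and TP63 from 8582 ± 10720 to 3387 ± 5052, and the 4 lung epithelial markers fell (4 over the list alone; adjusted p = 0.0171). In that library TP63 stood at 4073 against a mean of 11760 in its replicates and KRT5 at 81.7 against 158.6. AVIL, at 84.55 against 18.86, and AGER, at 162.3 against 2.625, were higher in it. Genes known to rise with BET inhibitors rose in 8 of 10 cases and fell in 1 (8 and 1 over the list alone; median 1.31, adjusted p = 0.00197). CHGA, low in these clones, rose from 18.8 ± 11.5 to 49.7 ± 20.3, and the neuroendocrine score rose in 10 of 22 cases and fell in 3 (11 and 5 over the list alone; adjusted p = 0.0591, but adjusted p = 2.86e-10 with an estimated correlation, which was negative). Without that library the score rose in 12 cases and fell in 4 and passed its test (adjusted p = 0.0254).

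Whether the response to JQ1 depends on NEUROD1 was tested as the difference between the responses of the 2 genotypes. The responses correlated across genes (r = 0.725); 2532 genes rose and 2731 fell in both, where independent lists would share 867.7 and 1013, and 84 were called in opposite directions. The difference itself passed the test for 490 genes, 245 with a higher and 245 with a lower response in knockout clones, of which 191 differed at least 2-fold. GFAP, an intermediate filament of glia, fell with JQ1 in knockout clones (-2.74, SE 0.16) but not in control clones (0.35, adjusted p = 0.0993), a difference of -3.09 (SE 0.22, adjusted p = 0.00872). EPHB3, an ephrin receptor, rose in control clones from 2.54 ± 1.36 to 38.1 ± 26.7 and stood at 599.8 ± 452.3 and 422.6 ± 240.9 in knockout clones (difference -3.95, SE 0.35, adjusted p = 0.0149). SYT12 rose by 2.49 in control clones and fell by 1.38 in knockout clones, and TMEM178A fell by 2.98 in control clones and rose by 1.47 in knockout clones. SRRM3, a splicing factor of neuronal microexons, fell from 67.8 ± 58.3 to 8.18 ± 8.04 in knockout clones and stood at 187.2 ± 39.7 and 244.5 ± 39.5 in control clones (difference -3.73, SE 0.70, adjusted p = 0.0394). SLC15A3, CD5, RPH3A and CHRNA1 fell with JQ1 in control clones and stood at 0.579 normalized counts or lower in knockout clones with DMSO, where a fall cannot be measured.

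Several neuroendocrine genes had a higher response without NEUROD1. SYN1, the vesicle protein synapsin 1, rose from 8.98 ± 5.59 to 39.7 ± 22.6 in knockout clones and stood at 601.8 ± 110.0 and 707.7 ± 152.9 in control clones (difference 1.86, SE 0.21, adjusted p = 0.0149). CHGA differed by 1.01 (SE 0.18, adjusted p = 0.0348), and 4 of 22 genes of that score had a higher and 0 a lower response (8 and 3 over the list alone; adjusted p = 0.0724, but adjusted p = 8.68e-13 with an estimated correlation, which was negative). Without the library that stood apart 8 had a higher and 2 a lower response, and the score passed its test (adjusted p = 0.00805). Peptide hormone genes had a higher response in 1 of 11 cases and a lower one in 3 (1 and 3 over the list alone; adjusted p = 0.0227). VGF rose 2.60 in control and 0.58 in knockout clones and SCG2 fell by 1.83 in knockout clones alone (difference -2.01, adjusted p = 0.0313). Ribosomal protein genes had a lower response in 11 of 64 cases (59 over the list alone; median -0.31, adjusted p = 3.54e-26, but adjusted p = 0.146 with an estimated correlation; 27 without the library that stood apart), with RPS15 at -0.74 (SE 0.13). G2/M genes fell less in knockout clones (median difference 0.37, adjusted p = 1.45e-09, but adjusted p = 0.694 with an estimated correlation), where FOXM1 (0.79) and NEK2 (0.67) were the 2 of 46 that passed singly (5 over the list alone; 4 without the library that stood apart). G1/S genes had a lower response in 7 of 55 cases and a higher one in 0 (18 and 1 over the list alone; median -0.22, adjusted p = 2.99e-06, but adjusted p = 0.146 with an estimated correlation). In knockout clones they fell in 29 cases and rose in 9 (30 and 10 over the list alone; adjusted p = 0.0268, but adjusted p = 0.484 with an estimated correlation and 0.106 without that library). Of 10 genes known to rise with BET inhibitors 3 had a lower response in knockout clones (5 lower and 1 higher over the list alone; adjusted p = 0.000393), SERPINI1, SAT1 and HIST1H2BK. In DMSO these 3 were already higher in knockout clones (7.52, 5.87 and 1.48), where 5 of the 10 were higher and 0 lower (6 and 1 over the list alone; median 1.43, adjusted p = 0.000366). MYC (0.50, adjusted p = 0.153), HEXIM1 (-0.33, adjusted p = 0.117) and NEUROD1 (-0.05, adjusted p = 0.904) did not pass.

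The number of genes with a different response, SYN1 and GFAP among the 490, varied with the clones and the test. With limma 0 genes passed without control clone 3, 10 or 13 (2502, 2385 and 2627 at an unadjusted p under 0.05; edgeR 0, 0 and 0; DESeq2 488, 372 and 478). Without knockout clone 12, 15 or 2-1 limma gave 1213, 57 and 886 (edgeR 1015, 0 and 84, DESeq2 1934, 784 and 1756). All 490 kept their sign and an unadjusted p under 0.05 with limma in each of these cases. They were chosen by their p in the full data, and each case reuses all clones but 1. This agreement was therefore largely set by the choice and does not bear the 490 out. The full data gave 3653 at an unadjusted p under 0.05, 12 genes with edgeR and 1046 with DESeq2. Without the library that stood apart 1164 genes passed, 454 of the 490 among them, while 304 passed without replicate 1 of control clone 13 with JQ1, and 85 and 93 without replicates 2 and 3 of knockout clone 12 with JQ1.

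**Figure D5:**
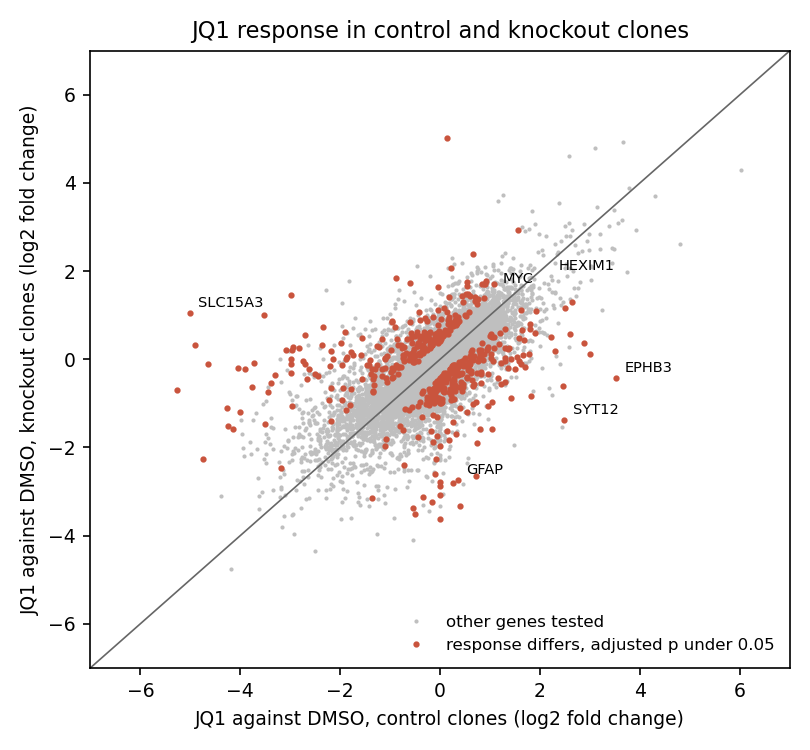
log2 fold change with JQ1 in control clones (horizontal axis) and in knockout clones (vertical axis) for each of 15819 genes; red points mark the 490 whose response differed at an adjusted p under 0.05 and the line marks equal responses. The correlation across genes is 0.725, EPHB3 and SYT12 lie under the line and SLC15A3 above it.

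The relation between the effect of losing NEUROD1 and the effect of JQ1 in control clones asks whether both touch the same transcripts. Of genes lower in knockout clones, 399 also fell with JQ1 and 150 rose, where independent lists would give 245.1 and 226.4; of genes higher in knockout clones, 260 rose and 223 fell, where independent lists would give 229.9 and 248.8. RPH3A, CHRNA3 and BHLHE22 were among the genes lower in both, and SAT1 and HIST1H2BC among those higher in both, whereas HES6 fell without NEUROD1 (-3.09) and rose with JQ1 (1.89). Across 15819 genes Pearson's r was 0.161 and Spearman's rho 0.128, and genes are not independent replicates. Both effects use the same control libraries with DMSO, and unchanged groups simulated against them gave a mean r of 0.237 (highest 0.271 of 100 draws), a value for no effect in either comparison. For the same reason, independent lists are not the value for no effect in the counts above. Genes near 0 in control clones also cannot show a fall with JQ1. The covariance was 0.182 against a simulated 0.0331 (highest 0.0387), a difference of 0.149, and with the control libraries split between the effects r was 0.141 and the covariance 0.163. The split leaves libraries of the same control clones on both sides. It removes shared noise of single libraries but not deviations of a whole clone with DMSO, so it cannot exclude the shared controls as a source.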

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

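Of the tests here, the 3 on the library that stood apart and the 1 that leaves it out of the difference in response were chosen only after the result was seen.

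The library of knockout clone 12 with JQ1, replicate 1, lay far from its replicates and held CEACAM6 (46010 normalized counts), SFTPA2 (12390), the collagen COL3A1 (32670) and the leukocyte marker PTPRC (1569). In it 1326 protein-coding genes at 1 FPKM or more were under 0.1 FPKM in both replicates, which argues against incomplete poly(A) selection alone, although short non-coding RNAs had a median log2 ratio of 8.66. Of these, 387 were under 0.1 FPKM in each of the other 35 libraries, while no other library held more than 1 such gene, which argues against less JQ1 or a mix-up within the series; a first version on the normalized counts was void, since that table kept only genes whose second-highest value was at least 7.99. All 13 blood, stroma and lung markers that were under 10 in its replicates were at 10 or more in it (100%; at most 8 in any other library), which is consistent with RNA of another human sample, with lung epithelium, mixed in. Of genes at 10 FPKM or more in it and under 0.1 FPKM in every further library but 1, 38 of 70 had a value in control clone 13 with JQ1, replicate 1 (0.239% of the level), against at most 8 of 49 in any other (at most 0.192%, in knockout clone 12 with DMSO, replicate 1); such traces stay open, and no biological explanation was tested.

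The 1985 genes that differed between genotypes in DMSO, such as SEZ6L and PDK4, could reflect the edit or differences that clones carry from the single cells they grew from. Removing the running median of 51 genes kept 93.06% of the 1946 called genes with a position past the threshold with the same sign. This argues against copy number of chromosome regions as the whole cause, and 2605 genes passed after the removal. Regional shifts were present: the running median, averaged over knockout clones, was beyond 0.3 in either direction for 6.75% of placed genes and 8.89% of the called ones. It ran from -0.63 to 3.784. The window shortens at chromosome ends, so these extremes need not be medians of 51 genes, and the highest value was not interpreted. The median log2 ratio of a chromosome to control clones reached -0.457 (chromosome 22) and -0.416 (chromosome 2) in knockout clone 12. Among control clones it reached -0.281 (clone 13, chromosome 11). The 6 clones allow 10 splits, which cannot give a share under 0.05; the real split gave 1985 genes and the highest other 2 (1 of 10 with as many), and with JQ1 1893 and 0 (1 of 10). Differences between clones unrelated to NEUROD1 stay open, since no clone with NEUROD1 restored was analysed here. Every knockout clone carried the same NEUROD1 guide RNA, per the labels. Effects of that guide away from NEUROD1 would be shared by all of them, so they stay open too.

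The response to JQ1 differed between genotypes for 490 genes. Of these, 12.9% had a mean under 10 in DMSO in 1 genotype only, against 8.7% of all genes tested, so a floor may account for part of them and leaves most open. Of the 490, 207 (42.2%) also differed between genotypes in DMSO, against 12.5% of all genes tested. The gap between genotypes was smaller with JQ1 for 63.5% of the 490, against 52.1% of all. These shares use the same DMSO libraries as the difference in response, so no cause follows from them. The library that stood apart is argued against as the source, since 92.65% of the 490 stayed past the threshold with the same sign without it. The 6 clones allow 10 splits, which cannot give a share under 0.05; the real split gave 490 genes and the highest other 0 (1 of 10 with as many).

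Single genes whose response differed, with the difference on the log2 scale (knockout minus control), were SLC15A3 (6.05, and 5.28 without the library that stood apart), CD5 (4.53, and 3.84 without it), TMEM178A (4.45), TRDC (3.65), HEPACAM2 (3.23), NAALADL2 (3.17), CCDC141 (3.13), SYT6 (3.08), BHLHE22 (2.94) and CTD-2116F7.1 (2.81, but -1.38 with edgeR and -0.36 with DESeq2). In the other direction were EPHB3 (-3.95), SYT12 (-3.87), SRRM3 (-3.73), ACTBL2 (-3.62), GFAP (-3.09), RHOH (-3.08), HSF2BP (-3.07), ASB4 (-3.07), CHRNA9 (-3.02, but 0.76 with edgeR) and SERPINI1 (-2.90). Their adjusted p (limma) ran from 0.00872 for GFAP to 0.048 for CTD-2116F7.1. By the rule for named genes, all 3 knockout clones lay on 1 side of all 3 control clones. Of these 20 genes, 14 had a mean under 10 in DMSO in 1 genotype only (all but NAALADL2, CCDC141, BHLHE22, SRRM3, GFAP and HSF2BP).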

How the results depend on the processing

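Leaving out the 2 libraries with foreign transcripts together was chosen only after the result was seen. The other alternatives of this part were planned, apart from edgeR and DESeq2 with 1 clone left out, for which no plan is recorded. Genotype in DMSO (1985 genes) gave 3816 with single libraries as replicates and 3327 with DESeq2, and 906 to 2033 when 1 clone or library was left out. Genotype with JQ1 (1893) gave 3347, 3054 and 760 to 1918. JQ1 in control clones (7572) gave 2002 with a 2-fold minimum and 4945 to 8966 when 1 clone or library was left out, and JQ1 in knockout clones (7845) gave 1869 with a 2-fold minimum. The other counts of these 4, apart from those with a replicate block given below, lay within 1.5 times of the value reported.

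The difference in response (490) gave 211 with FPKM, 93 with a constant prior variance, 4503 with single libraries, 12 with edgeR, 1046 with DESeq2, 191 with a 2-fold minimum, 894 without both libraries with foreign transcripts and 0 to 1213 when 1 clone or library was left out. With limma 0 genes passed without control clone 3, 10 or 13 (2502, 2385 and 2627 at an unadjusted p under 0.05; edgeR 0, 0 and 0; DESeq2 488, 372 and 478). Without replicates labelled 2 it was 129 and without replicates labelled 3 it was 70. Without 1 knockout clone limma gave 1213 (clone 12), 57 (clone 15) and 886 (clone 2-1). Having fewer clones lowers the degrees of freedom, but equally in these cases, so that alone cannot account for the counts of 0. The cause was not tested for any of these settings.

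Replicate numbers did not pair the libraries: the correlations of deviations over 18 pairs lay between -0.038 and 0.046. With a replicate block the single-library counts were 3688 (genotype, DMSO), 3192 (genotype, JQ1) and 3818 (difference in response).

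Of 190 list tests, 69 passed with the preset correlation and 40 with an estimated one (32 shared). The correlation of the knockout and JQ1 effects (0.161) was 0.144 for genes with a mean of at least 50, 0.141 with split controls and 0.154 to 0.161 when 1 knockout clone was left out.

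For named genes, 2274 of 2455 values kept direction and side of the threshold, 148 lost the call, 11 gained it and 22 changed sign. The 20 response differences each lost the call under at least 1 alternative. CTD-2116F7.1 changed sign in the response difference with edgeR (-1.38) and DESeq2 (-0.36), and CHRNA9 with edgeR (0.76). The other sign changes were of genes with no call: BCL2 for genotype in DMSO with FPKM (-0.006) and NEUROD1 in the response difference with a pseudocount of 0.5 (0.017), edgeR (0.132) and DESeq2 (0.13). When 1 clone, replicate number or library was left out, BCL2 ran from -0.106 to 0.356 (genotype, DMSO), -0.365 to 0.43 (genotype, JQ1) and -0.259 to 0.131 (response difference). NEUROD1 ran from -0.101 to 0.557 (JQ1, knockout clones) and -0.314 to 0.317 (response difference). The cause was not tested.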

Other observations

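Of the tests in this part, the values without the library that stood apart and the choice of IGF2 came only after the result was seen. The lists of p53 targets, of BET proteins with transcription elongation and of the Wnt pathway, some of whose members are described above, were tested with JQ1. Of 25 p53 target genes, 13 rose and 4 fell in control clones (13 and 5 over the list alone; median 0.42, adjusted p = 0.0268, but adjusted p = 0.0561 with an estimated correlation), and 13 rose and 5 fell in knockout clones (13 and 5 over the list alone; adjusted p = 0.0462, but adjusted p = 0.0713 with an estimated correlation). Genes of BET proteins and transcription elongation rose in 15 of 27 cases and fell in 4 in knockout clones (16 and 4 over the list alone; median 0.23, adjusted p = 0.0191, but adjusted p = 0.465 with an estimated correlation). In control clones 9 rose and 6 fell (10 and 6 over the list alone; adjusted p = 0.357), and the difference between genotypes did not pass (adjusted p = 0.12) except without the library that stood apart (adjusted p = 0.0122). Wnt pathway genes fell in 10 of 17 cases and rose in 2 in knockout clones (10 and 2 over the list alone; median -0.74, adjusted p = 0.024, but adjusted p = 0.0713 with an estimated correlation). In control clones 6 of them fell and 3 rose (6 and 3 over the list alone; adjusted p = 0.286), and the difference between genotypes did not pass (adjusted p = 0.477). IGF2, a growth factor, stood at 0.589 ± 0.251 in knockout clones with DMSO and at 47.1 ± 5.91 with JQ1 (difference in response 4.88, adjusted p = 0.0149).

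Among 100 splits of the libraries within clones, the real one gave the most genes with JQ1 in both genotypes (1 of 100 each). In control clones it gave 7572 and the highest other 2094, in knockout clones 7845 and 5789. The splits exchange libraries within clones, while the clone was the replicate in the tests. They therefore cannot decide what chance differences between clones would give. The split with 5789 genes kept 8 of the 9 JQ1 libraries of knockout clones under their real label, so its count comes from the JQ1 response itself.

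The response to JQ1 correlated at 0.783 to 0.825 between pairs of control clones and at 0.478 to 0.487 between knockout clone 12 and the control clones, or 0.59 to 0.591 without its library that stood apart. For knockout clones 15 and 2-1 with the control clones it was 0.613 to 0.672, and between knockout clones 0.532 to 0.769, or 0.69 to 0.769 without that library; genes are not independent replicates.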
